A study of Escherichia coli and Escherichia coli
Bdellovibrio bacteriovorus and Bdellovibrio bacteriovorus with 30 samples.

How the data were processed

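Transcript levels of E. coli genes were read on nylon macroarrays in 3 groups of 5 biological replicates. The authors mixed prey and predator after both had been incubated separately in buffer, took samples at 15 minutes, primed cDNA with E. coli labelling primers and labelled it with phosphorus-33, per the labels' protocols. The membranes were scanned to images and read with ArrayVision, per the series' design text; its version is not given in the sources used here. Per the file headers, each deposited scanner table holds spot density (a linear intensity), 1 background density for the array and a background-subtracted density, for an E. coli only reading and for the array set beside it. The table of infected replicate 1 states no background. Group and replicate came from the labels, and the design text told which column of each file belonged to which group.

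The deposited value table holds, for each array, each spot as a share (fraction) of the summed density of its gene spots, without background subtraction. This was found by setting its columns against the scanner densities, since the labels do not state it; scale and centring follow from that match, and a direction does not apply. Of its 15 column pairs 10 matched a scanner reading in 120 of 120 values tested. These matches also tied all 4290 probe IDs to their spot pairs, with a largest natural-log difference of 0.0028 to the matched pair against 0.125 to the next one, and left 312 of 4602 spot pairs without a probe ID, which were not analysed as genes. Replicate numbers in the value table were shifted against those of the scanner files. The reading deposited as Bdellovibrio only replicate 4 stood in the value table under an infected label. The value-table columns of Bdellovibrio only replicates 4 and 5 repeated 2 E. coli only columns at 2.00 times their values and were left out. Scanner files were therefore the main source and the value table an alternative.

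Probe names came from the platform annotation supplied with the series. It gave 1 symbol for 4095 probes and several for none, and 195 probes are unnamed here. Of the named probes 4094 were found by gene ID in the MG1655 reference table (ASM584v2), with 0 symbols changed. Gene coordinates are not given because no source names the build for strain S17-1.

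Densities were corrected with limma's normexp method (offset 50), fitted on all spots, log2 transformed and quantile normalised between the arrays of each fit. The 2 spots of a probe were then averaged. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) tested infected against E. coli only in a fit of those 10 arrays, and tested Bdellovibrio only against E. coli only and infected against Bdellovibrio only in a fit of all 15 arrays, 2-sided, at a Benjamini-Hochberg adjusted p under 0.05. A gene was counted outside both controls when infected passed against each of them in the same direction. A probe was called above background on an array when both spots had a background-subtracted density over 0. Infected replicate 1 was left out of these calls, because its file states no background and the background-subtracted density there rests on another one: E. coli only replicate 1 as read in that file had 68.2% of spots over 0, against 91.1% in its own file. No dim probe was left out of the tests.

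A total of 33 gene lists, with 1171 memberships of which 1128 had a probe, was tested with limma's camera at a preset correlation between members of 0.01, with an estimated correlation beside it; adjustment was over the lists. Former gene names were matched through the synonyms of the reference table. With limma's fry, 0 lists passed in either comparison. The gene tests, the lists, their test in infected against E. coli only and most alternatives were fixed before the data were examined; testing the lists in the comparisons with Bdellovibrio only was added after. Genes were named by a rule fixed then too. It took the 12 largest changes in each direction past the threshold that go the same way in all 5 replicate numbers or, where fewer than 5 qualify, the 10 smallest p in that direction, said not to have passed. From each list it took up to 4 members with the smallest p, and from Bdellovibrio only against E. coli only the 6 largest changes in each direction past the threshold. Naming 4 members for the lists that passed and 1 for the others was decided after the data were seen.

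The tests were tried on simulated data with the real means and spreads, in 10 runs with 200 of 4290 genes changed. For infected against E. coli only they called 36.0% of genes changed 2-fold, 81.6% of those changed 4-fold, 95.0% at 8-fold and 98.6% at 16-fold, with 10.2 false calls per run. For Bdellovibrio only against E. coli only the shares were 33.4%, 82.0%, 94.6% and 98.6%, with 8.4 false calls. Genes were drawn independently in these runs. With 200 genes changed at once the Benjamini-Hochberg threshold is laxer than in the real data, where 1 gene passed. These shares therefore do not show the power of the real comparisons. There thrB, with a log2 change of 2.74 in infected, had a limma adjusted p of 0.9997. In 20 simulated runs without change camera called a list in 0; genes were drawn independently there, so these runs do not show how often lists are called when members vary together. In 20 runs with amino acid biosynthesis raised by 0.3 on the log2 scale it called that list in 20.

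Alternatives were plain background subtraction (with a floor at the 5th percentile of positive values, and the deposited background-subtracted density for infected replicate 1) or none, median scaling, shares of summed signal, no normalization between arrays (run only for the comparisons with Bdellovibrio only), leaving out the dimmest 33.3% of genes, the replicate number as a block, leaving out each replicate in turn, the value table, the E. coli readings stored beside the infected ones, a fit of all 3 groups, a prior variance with an intensity trend, and spots kept apart with duplicateCorrelation. Per the series' design text, membranes were used again with the samples swapped. The membrane as a block was not run, because the files do not tell which membrane each hybridisation used. Dependence between arrays through shared membranes was therefore not tested. Added after seeing the data were 2 other labellings of the replicate 4 readings, the arrays that both sources put in 1 group, all distinct readings together, and array quality weights. In 1 labelling the reading deposited as Bdellovibrio only replicate 4 took the place of infected replicate 4, which was left out. In the other these 2 arrays were exchanged. Of the arrays in 1 group in both sources, E. coli only gave replicates 2 to 5 and infected replicates 2, 3 and 5. Bdellovibrio only gave replicates 2 and 3.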

Results

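Bdellovibrio bacteriovorus is a predatory bacterium that attaches to other Gram-negative bacteria, enters their periplasm and consumes them from within. The samples addressed how transcript levels of Escherichia coli S17-1, a laboratory K-12 derivative, differed 15 minutes after mixing with the predator strain 109J. Total RNA was taken from 3 groups. "E. coli only" held prey with cell-free predator supernatant, "infected" held prey with predator, and "Bdellovibrio only" held predator with cell-free prey supernatant. Each group had 5 biological replicates, and each replicate was 1 hybridisation to a nylon macroarray of E. coli gene probes, on which each probe is printed as 2 spots. Per the labels, the 30 deposited samples are 2 technical replicates of each biological replicate, although both samples of infected replicate 3 are labelled technical replicate 2. The label was phosphorus-33, carried by cDNA made with E. coli labelling primers.

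Signal differed widely between arrays. The median spot density was 1.24 to 3.13 times the array's background in E. coli only, 1.52 to 1.93 times in the 4 infected arrays whose files state a background, and 1.06 to 3.03 times in Bdellovibrio only. Bdellovibrio only replicate 5 was the faintest array, with 4.29% of spots above 2 times its background, whereas Bdellovibrio only replicate 1 had 68.1% above that level. The number of arrays limits the precision of every value that follows.

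**Figure D1:**
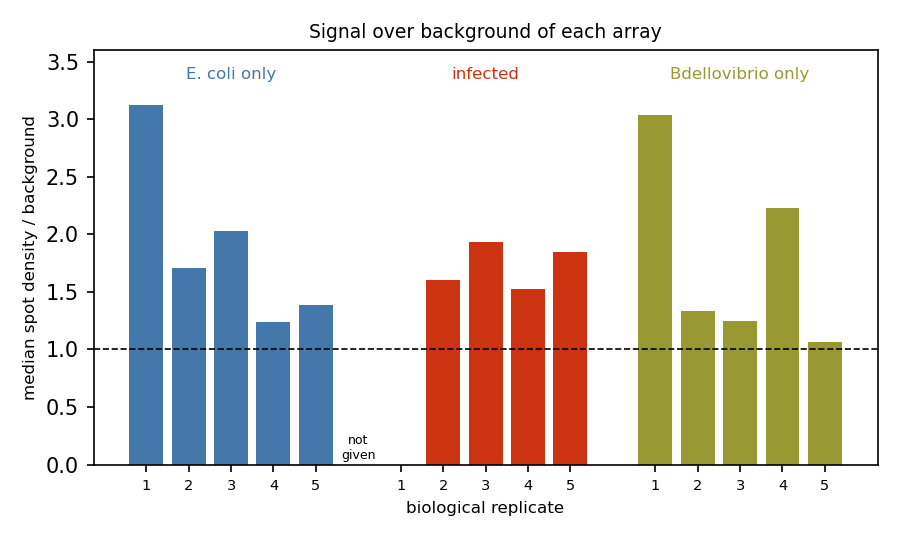
Median density of the gene spots divided by the array's background density, 1 bar per array, in the 3 groups of 5 biological replicates; the dashed line marks a density equal to background. Infected replicate 1 has no bar because its file gives no background. Bdellovibrio only spans 1.06 to 3.03.

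Among 4290 probes, degS was the one gene that differed between infected and E. coli only. It encodes an inner-membrane-anchored periplasmic protease that first cleaves the anti-sigma factor RseA and so starts the sigma E envelope stress response. Its normalised log2 intensity was 12.69 ± 1.09 (SD, n = 5) in infected and 8.37 ± 0.65 (SD, n = 5) in E. coli only, a rise of 4.32 (SE 0.50) on the log2 scale or 20.0-fold (limma, Benjamini-Hochberg adjusted p = 0.00926). All 5 infected replicates lay above every E. coli only replicate. The degS spots were above background on the 4 infected arrays with a stated background and on 3 of the 5 E. coli only arrays. No gene fell. In limma, 125 probes had an unadjusted p under 0.05 against 214.5 given by chance, 75 of them higher and 50 lower in infected. Without single replicates this count ran from 88 (infected replicate 4) to 189 (infected replicate 1). The next smallest limma adjusted p was 0.9997. The degS call was absent in the fit of all 3 groups (log2 change 4.15, adjusted p = 0.368). That fit uses 1 estimate of the spread for all groups, and degS ran from 7.82 to 13.6 over the Bdellovibrio only arrays. The call was also absent in the deposited value table (log2 change 2.77, adjusted p = 0.907) and without infected replicate 1 (log2 change 4.26, adjusted p = 0.0591). The scanner files and the value table label 1 replicate 4 reading differently. In settings added after seeing the data, the degS call was absent when this reading, deposited as Bdellovibrio only, replaced infected replicate 4 (log2 change 3.62, adjusted p = 0.308). With the 3 groups normalised together, degS was at 9.86 in that reading and at 13.3 in the infected array left out. The call was also absent with only the arrays of 1 group in both sources (log2 change 3.865, adjusted p = 0.999). Of the infected arrays that setting kept replicates 2, 3 and 5. Over the settings run for this comparison the limma adjusted p ran from 4.78e-07 to 0.999. The low end came from keeping the 2 spots of each array apart. With spots averaged the lowest was 0.000934, without infected replicate 2.

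The 9 genes next to degS among those with the smallest p on the higher side did not pass the test, and their values are given without a call. They include genes of metabolism and transport. For thrB, the homoserine kinase of threonine synthesis, the log2 change was 2.74 (SE 0.69), and for leuA, the first enzyme of the leucine branch, it was 1.23 (SE 0.31). For eutP, an ethanolamine utilisation gene, it was 1.87 (SE 0.43), for nikB, a nickel transport permease, 1.25 (SE 0.33), and for yadH, a predicted transporter permease, 1.74 (SE 0.51). The remaining values were 2.71 (SE 0.64) for pgrR, a LysR-type regulator, 2.07 (SE 0.48) for ykgF, 1.40 (SE 0.38) for msrB, a methionine sulfoxide reductase, and 0.78 (SE 0.24) for ybcK of a defective prophage. Each of these genes was higher in infected in all 5 replicate numbers. On the E. coli only arrays eutP, ykgF and msrB were above background in 3 of 5, and pgrR and yadH in 4 of 5. With spots kept apart pgrR passed the test as well. That fit takes the 2 spots of an array, whose consensus correlation was 0.823, as separate observations, and such spots are not biological replicates.

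On the lower side none of the 10 genes with the smallest p passed either. The log2 change was -1.44 (SE 0.35) for ihfA, a subunit of the nucleoid protein IHF, -1.36 (SE 0.35) for pfkA, the main phosphofructokinase of glycolysis, and -0.72 (SE 0.20) for katE, the stationary-phase catalase HPII. It was -0.92 (SE 0.27) for cmoB, a tRNA modification enzyme, -1.06 (SE 0.31) for hyaF of the hydrogenase 1 operon, and -1.51 (SE 0.51) for csdE, a sulfur acceptor. Values of -1.31 (SE 0.33), -1.40 (SE 0.41) and -1.14 (SE 0.37) belonged to yebV, ygiS and yecR, and -0.84 (SE 0.26) to probe 392, which is unnamed here. For csdE 1 of the 5 replicate numbers went the other way. On the 4 infected arrays with a stated background yebV and pfkA were above it in 1, cmoB in 2 and katE and csdE in 3.

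**Figure D2:**
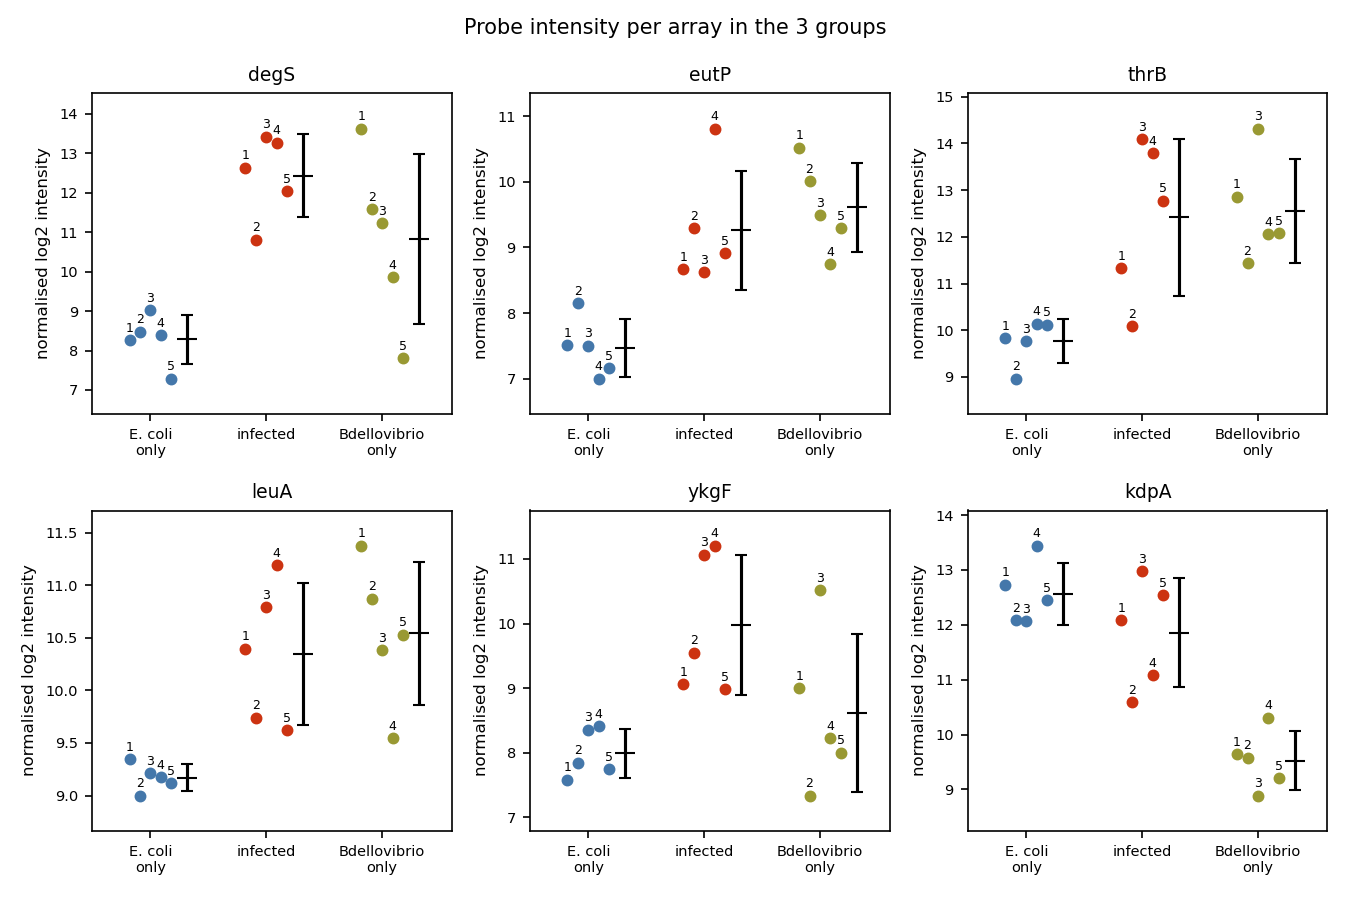
Normalised log2 intensity of 6 probes on each array, with the 3 groups normalised together; digits give the biological replicate, and bars give the mean ± SD of 5 arrays. For degS all 5 infected arrays and 4 of the 5 Bdellovibrio only arrays lie above every E. coli only array, and for kdpA all 5 Bdellovibrio only arrays lie below every E. coli only array.

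Of 33 gene lists, 4 passed camera at its preset correlation in infected against E. coli only, and none did with an estimated correlation. The general stress list, genes of the RpoS regulon of starved and stationary cells, was lower in infected, with 24 of 31 measured members lower, a median log2 change of -0.27 and a camera adjusted p of 0.00265 (adjusted p = 0.467 with an estimated correlation). Amino acid biosynthesis was higher, with 65 of 89 members higher and a median of 0.16 (adjusted p = 0.00612; adjusted p = 0.467 with an estimated correlation). Nucleotide biosynthesis had 24 of 31 members higher and a median of 0.18 (adjusted p = 0.0328; adjusted p = 0.504 with an estimated correlation), and fatty acid and phospholipid synthesis had 19 of 26 members higher and a median of 0.14 (adjusted p = 0.0328; adjusted p = 0.467 with an estimated correlation). No member of any list passed limma's test over all genes, and 0 passed when adjusted over the list alone, with 7 members of amino acid biosynthesis, 1 of nucleotide biosynthesis, 1 of general stress and 0 of fatty acid and phospholipid synthesis at an unadjusted p under 0.05. The number of lists called fell to 2 without E. coli only replicate 1 or infected replicate 2 or 4 and to 1 without E. coli only replicate 2, was 6 without infected replicate 3, and was 2 in the value table and 0 with arrays of 1 group in both sources.

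Individual members of the 4 lists are therefore given as values only. In the general stress list the smallest p belonged to katE, followed by yciE (log2 change -1.81, SE 0.93), osmE (-0.71, SE 0.41), an osmotically inducible lipoprotein, and yciF (-0.42, SE 0.24). Amino acid biosynthesis was headed by thrB and leuA, with cysP, a sulfate-binding protein, going the other way (-1.06, SE 0.41) and metL, an aspartokinase and homoserine dehydrogenase, at 0.94 (SE 0.37). Among the nucleotide genes purA, the adenylosuccinate synthase, was at 0.53 (SE 0.23), cmk at 0.56 (SE 0.26), pyrE at 0.48 (SE 0.23) and guaB, the IMP dehydrogenase, at 0.50 (SE 0.25). In the lipid list cfa, the cyclopropane fatty acid synthase, was at 0.45 (SE 0.21), accC at 0.53 (SE 0.27), plsC at 0.39 (SE 0.22) and pgsA at 0.40 (SE 0.27). On the E. coli only arrays cmk was above background in 1 of 5 and metL in 2 of 5.

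In a test added after seeing the data, the same 4 lists stood apart in Bdellovibrio only against E. coli only. Their medians were -0.43 for general stress, 0.32 for amino acid biosynthesis, 0.41 for nucleotide biosynthesis and 0.33 for fatty acid and phospholipid synthesis, each farther from 0 than in infected, although no list passed camera in infected against Bdellovibrio only (smallest adjusted p = 0.106). Camera gave adjusted p = 0.000165, adjusted p = 0.000201, adjusted p = 0.00114 and adjusted p = 0.00385 in that order. With an estimated correlation these became adjusted p = 0.193, adjusted p = 0.419, adjusted p = 0.478 and adjusted p = 0.419. Bdellovibrio only replicate 5, the faintest array, lay farthest from E. coli only in all 4 lists; without it the medians were -0.41, 0.20, 0.27 and 0.31, and the 4 lists passed camera at adjusted p = 0.000404, adjusted p = 0.0102, adjusted p = 0.0311 and adjusted p = 0.0252. Fatty acid and phospholipid synthesis did not pass with median scaling (median 0.17, adjusted p = 0.160) or shares of summed signal (adjusted p = 0.0889), nor did nucleotide biosynthesis with shares (adjusted p = 0.0655). Without normalization, where the median over all probes was -0.59, general stress alone of the 4 passed, and the other 3 had medians from -0.45 to -0.37. Both comparisons share the E. coli only arrays. Adjusted over the list alone, 2 members of general stress, 2 of amino acid biosynthesis, 1 of nucleotide biosynthesis and 0 of fatty acid and phospholipid synthesis passed in Bdellovibrio only, against 0 over all genes.

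**Figure D3:**
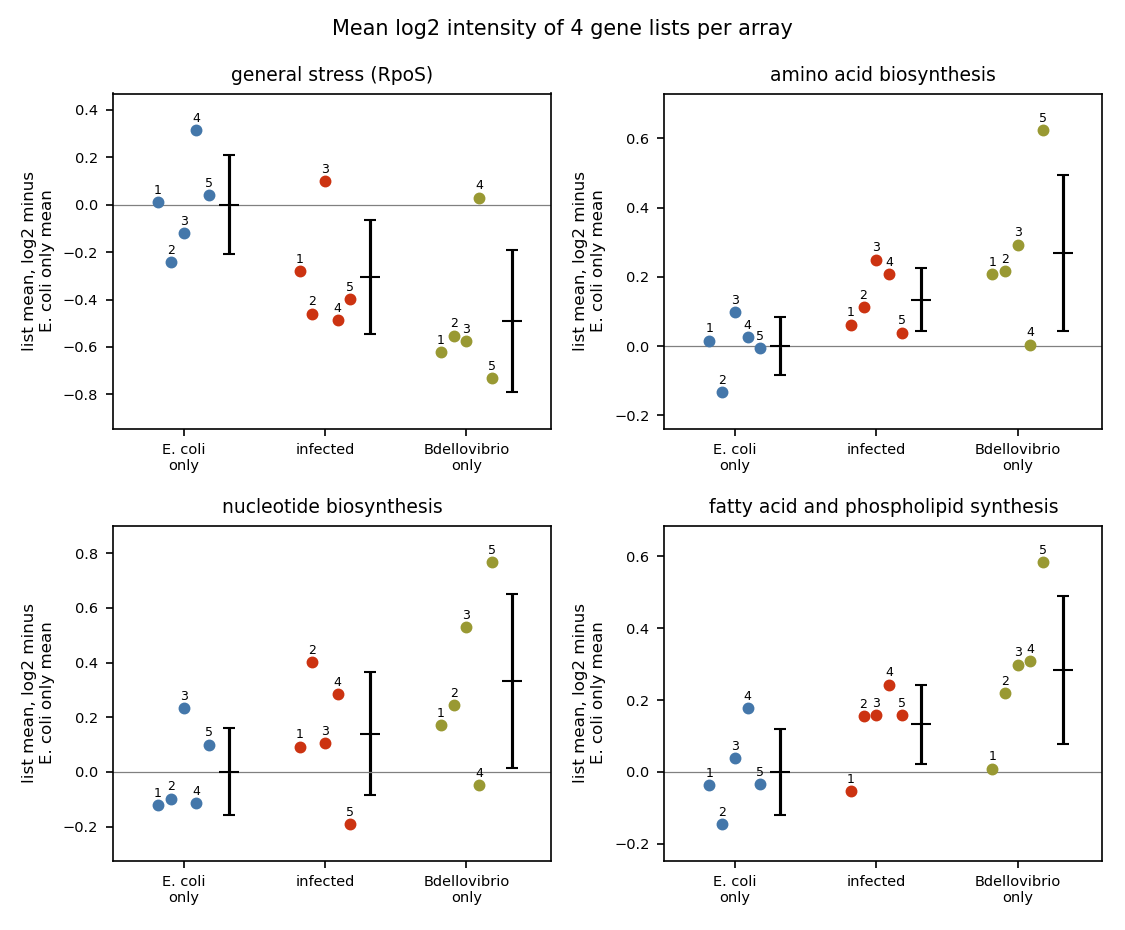
Mean over the members of each list of log2 intensity minus that member's E. coli only mean, per array, with the 3 groups normalised together; digits give the biological replicate and bars the mean ± SD of 5 arrays. For general stress the group means are -0.31 in infected and -0.49 in Bdellovibrio only, against 0 in E. coli only.

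The other 29 lists did not pass, with adjusted p from 0.112 to 0.914, and no direction is read from them. Envelope and stress responses were among them. Camera gave adjusted p = 0.179 for the phage shock list, whose member with the smallest p was pspA (log2 change -0.68, SE 0.32), and adjusted p = 0.199 for heat shock, with the protease subunit gene hslV at 0.64 (SE 0.23). Sigma E targets gave adjusted p = 0.373, with the periplasmic chaperone gene surA at -0.80 (SE 0.48), and the Cpx list gave adjusted p = 0.869, with ppiD at 0.43 (SE 0.31). For Rcs and colanic acid the value was adjusted p = 0.179, with wzb at -0.53 (SE 0.21). Acid resistance reached adjusted p = 0.914, with hdeB at -0.57 (SE 0.36), oxidative stress adjusted p = 0.247, with sufD at 1.21 (SE 0.59), and SOS and DNA repair adjusted p = 0.367, with dinB at 0.57 (SE 0.24). The cold shock list had adjusted p = 0.709 and nusA at -0.91 (SE 0.66), and osmotic stress adjusted p = 0.331 and aqpZ, the aquaporin gene, at -0.66 (SE 0.27).

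Growth and energy genes likewise did not pass. Ribosomal proteins had adjusted p = 0.373, with rplE at 0.67 (SE 0.27), and the highly conserved housekeeping genes adjusted p = 0.373, with der, a ribosome assembly GTPase, at -0.57 (SE 0.26). For the tricarboxylic acid cycle the camera result was adjusted p = 0.306, with fumA at -1.50 (SE 0.60), for glycolysis adjusted p = 0.112, with pfkA as given earlier, for aerobic respiration adjusted p = 0.838, with atpC at -0.79 (SE 0.32), and for anaerobic metabolism adjusted p = 0.879, with narK at -0.64 (SE 0.32). Flagella and chemotaxis had adjusted p = 0.879, with fliE at 1.30 (SE 0.48), and fimbriae and curli adjusted p = 0.709, with yadM at 0.60 (SE 0.30).

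Cell surface lists gave adjusted p = 0.579 for peptidoglycan synthesis and turnover, with the amidase gene amiB at -0.41 (SE 0.28), adjusted p = 0.117 for outer membrane proteins, with slyB at -1.42 (SE 0.50), and adjusted p = 0.838 for lipopolysaccharide synthesis, with kdsB at -1.02 (SE 0.44). Nutrient lists gave adjusted p = 0.259 for iron uptake, with fepB of enterobactin transport at 2.05 (SE 0.72), adjusted p = 0.558 for phosphate starvation, with phnM at 2.47 (SE 0.86), adjusted p = 0.879 for nitrogen starvation, with rutB at -1.02 (SE 0.46), and adjusted p = 0.879 for carbon starvation. In the last of these the smallest p belonged to lacY, which was not above background on any of the 5 E. coli only arrays, so no level is compared. Efflux genes had adjusted p = 0.914, with emrB at 0.72 (SE 0.25). Prophage genes had adjusted p = 0.613, with ybcK as given earlier, toxin-antitoxin systems adjusted p = 0.655, with ykfI at 0.40 (SE 0.23), and insertion sequences adjusted p = 0.894 over 5 measured members, with insK at 0.39 (SE 0.28). In 4 lists (acid resistance, anaerobic metabolism, lipopolysaccharide synthesis and efflux) the median, the mean and the test differed in sign. On the E. coli only arrays hslV and insK were above background in 1 of 5 and fepB in 2 of 5, and on the 4 infected arrays with a stated background kdsB and surA were above it in 1 and slyB, atpC and der in 2.

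The Bdellovibrio only arrays show which E. coli probes gave signal without added prey, although leftover prey RNA was not measured. From 64.2% (replicate 5) to 99.2% (replicate 1) of gene spots were above background on these arrays. On the E. coli only arrays the share ran from 62.2% (replicate 4) to 98.4% (replicate 3), so it does not part the 2 groups. Quantile normalization forces the same distribution on all arrays, so few differing genes do not mean a like level of signal. Without normalization the median of Bdellovibrio only minus E. coli only over all probes was -0.59. Median spot densities ran from 284 to 3607 within E. coli only and from 181.13 to 2891.5 within Bdellovibrio only. Against that spread between arrays, the value does not measure the amount of E. coli RNA. In the fit of all 3 groups 1 gene differed from E. coli only. This was kdpA, which encodes the potassium-binding subunit of the Kdp uptake system and fell by 3.03 (SE 0.43) on the log2 scale (limma adjusted p = 0.0114), with all 5 Bdellovibrio only arrays below every E. coli only array. No gene was higher. In limma, 490 probes had an unadjusted p under 0.05 against 214.5 given by chance, 247 higher and 243 lower. Without single replicates this count ran from 362 (E. coli only replicate 4) to 737 (Bdellovibrio only replicate 4), and without normalization it was 84. The kdpA call was absent in the value table (log2 change -2.09, adjusted p = 0.141), where 19 other genes were higher and 10 lower, and without normalization between arrays (log2 change -3.79, adjusted p = 0.996). It was also absent without E. coli only replicate 1 (adjusted p = 0.0540) or 4 (adjusted p = 0.0509) and without Bdellovibrio only replicate 3 (adjusted p = 0.0576) or 5 (adjusted p = 0.0605). With the replicate number as a block the kdpA call was lost too (limma adjusted p = 0.0711). In settings added after seeing the data the call was absent with arrays of 1 group in both sources (log2 change -3.20, adjusted p = 0.339). Of the Bdellovibrio only arrays that setting kept replicates 2 and 3. The kdpA call was absent with all distinct readings as well (log2 change -2.26, adjusted p = 0.0934).

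Several probes that were brighter in infected than in E. coli only were also brighter with the predator alone, although none passed the test in the fit of all 3 groups. Bdellovibrio only minus E. coli only was 2.54 (SE 0.80, limma adjusted p = 0.306) for degS, 2.15 (SE 0.42, adjusted p = 0.196) for eutP, 2.78 (SE 0.67, adjusted p = 0.196) for thrB, 1.37 (SE 0.35, adjusted p = 0.212) for leuA and 2.44 (SE 0.73, adjusted p = 0.306) for yadH. For eutP, thrB, leuA and yadH all 5 Bdellovibrio only arrays lay above every E. coli only array, and for degS 4 of 5 did. With plain background subtraction (adjusted p = 0.0316), in the value table (adjusted p = 0.0228) and without infected replicate 4 (adjusted p = 0.0180) eutP passed, as it did under both other labellings of replicate 4, which were added after seeing the data (adjusted p = 0.00462 and adjusted p = 0.00147). Under the same labellings leuA passed as well (adjusted p = 0.0312 and adjusted p = 0.0119), and thrB passed with the arrays exchanged (adjusted p = 0.0448) but not with the value-table label (adjusted p = 0.0894). The difference was 0.63 (SE 0.55, adjusted p = 0.659) for ykgF and 0.41 (SE 0.41, adjusted p = 0.703) for nikB. Of the 20 genes named from infected against E. coli only, 20 had a Bdellovibrio only mean on the same side of E. coli only as the infected mean. The comparisons share the E. coli only arrays, which gave 16.4 of 20 on average, and up to 20 of 20, in simulations without any change. With those arrays split between the comparisons the median was 14 of 20 (range 5 to 18). The genes had been chosen against all 5 E. coli only arrays, so splitting these does not undo the choice. No chance level is given for the split counts, and nothing is concluded from them.

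Infected did not differ from Bdellovibrio only for any gene after adjustment. In limma, 244 probes had an unadjusted p under 0.05 against 214.5 by chance, 136 higher and 108 lower in infected (135 without infected replicate 3, 146 without Bdellovibrio only replicate 5 and 376 without Bdellovibrio only replicate 4), and the smallest adjusted p was 0.241. The degS difference was 1.61 (SE 0.80, adjusted p = 0.843); without single replicates it ran from 0.87 (Bdellovibrio only replicate 5) to 2.30 (Bdellovibrio only replicate 1), and it was 0.86 in the value table. In settings added after seeing the data it was 0.68 with replicate 4 labelled as in the value table, 0.25 with its arrays exchanged, 0.68 with arrays of 1 group in both sources and 0.76 with array quality weights. Without infected replicate 2 kdpA passed (log2 difference 2.67, adjusted p = 0.0407), and 2 or 5 genes did under other labels of replicate 4. No gene was higher, and no gene lower, in infected than in both controls, with 2 probes higher and 3 lower at an unadjusted limma p under 0.05 against each. At the level of group means without a test, infected lay between the controls for 2041 probes (47.6%), above both for 1115 and below both for 1134. No chance level is given for these counts, so nothing is concluded from them about mixing.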

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

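The tests of gene lists in Bdellovibrio only, of predator RNA, of transcription by the prey, of members varying together and of conserved sequence were chosen only after the results were seen; those of spill, brightness, sample splits and replicate 4 labels were set before their values were known.

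The rise of degS in infected stood beside a higher mean of the same probe in Bdellovibrio only. Bdellovibrio only minus E. coli only was 2.54 on the log2 scale for this probe (exact permutation p = 0.0397, 2-sided, n = 5 against 5; Benjamini-Hochberg adjusted over the 10 genes so tested, 0.0567), so predator RNA on the probe stays a candidate source of the signal, for a gene chosen through the same E. coli only arrays. Spill from brighter spots nearby was argued against, since a nearby spot was brighter than the degS spots in 1 of the 5 infected arrays. Transcription by the prey stays open, because infected exceeded Bdellovibrio only by 1.61 (exact permutation p = 0.183; 0.87 without Bdellovibrio only replicate 5 and 0.25 with the replicate 4 arrays exchanged) and leftover prey in the predator culture was not measured. Chance was not excluded for the count of calls either: 8 of 100 splits of the 10 arrays, the real one included, gave at least the 1 gene of the real split, and 1 other split, which set E. coli only replicates 1, 2 and 5 with infected replicates 1 and 2 against the rest, gave 4, a sign of structure among the arrays.

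The 4 list shifts in infected may also follow predator RNA in the mixed sample. With quantile normalization, in 4 of 4 lists Bdellovibrio only lay farther from E. coli only than infected did, also without any single Bdellovibrio only replicate, as a mixture needs; no list passed camera between infected and Bdellovibrio only (smallest adjusted p = 0.106), and a shared direction against E. coli only follows in part from how the lists were chosen. Members that vary together from array to array could account for the small p, since the smallest adjusted p with an estimated correlation was 0.467. On brightness of the members, 3 of the 4 lists lay outside the central 95% of random lists matched on intensity. The prediction set beforehand took that as against brightness as the whole cause. The lists had been chosen for standing apart from other genes in the same data, and random lists take no account of members that vary together. That result therefore does not decide the question. As many lists as the real 4 came from 5 of 100 splits of the arrays, the real one included, with up to 7 in another split and at least 1 list in 59, so chance was not excluded.

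Probes for E. coli genes gave signal on all Bdellovibrio only arrays, whose mean correlation across genes with E. coli only arrays ran from 0.474 (replicate 5) to 0.803 (replicate 4); genes are not independent replicates. Conserved sequence as the source cannot be told from other sources, because the list of highly conserved genes lay at the 5.81 percentile of matched random lists, inside their central range. In infected minus E. coli only this list lay at the 1.02 percentile, below that range. Camera did not call the list there (adjusted p = 0.373). Random lists take no account of members that vary together (estimated correlation 0.055), so that value decides nothing about the source. A swap of labels in replicate 4 stays open: over the 100 probes that best parted infected from Bdellovibrio only in the other replicates, its score was -0.67, on the exchanged side, but replicate 2 scored -0.56 as well, so the test decided nothing. Taken as 1 wrong label, Bdellovibrio only replicate 4 lay at 0.84 on the infected side, yet replicate 2 lay at 0.05 and replicate 3 at 0.0021 on that side too. No biological explanation of this signal was tested.

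For Bdellovibrio only against E. coli only 8 of 100 splits, the real one included, gave at least the 1 gene of the real split, so chance was not excluded. The split with replicates 1 to 3 of Bdellovibrio only and 1 and 2 of E. coli only on one side gave 57 genes, which points to a structure of the arrays other than the groups. As many lists as the real 7 came from 6 of 100 splits, the real one included, with up to 9 in another and at least 1 list in 66. For infected against Bdellovibrio only the real count was 0, so 100 of 100 splits gave as many, and the largest other count, 5, came from the split that exchanges the replicate 4 arrays, again a sign of structure. No gene lay outside both controls in the real grouping, as in 100 of 100 splits of the 15 arrays, whose highest count was 0.

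A single array stood far from the other 4 of its group in 6 of 204 groups of values examined, where chance gives about 5%, or 10.2. The log2 intensity of yadH was 11.93 in infected replicate 4, that of osmE was 11.80 in E. coli only replicate 4 and 8.92 in infected replicate 3, that of fumA was 12.27 in E. coli only replicate 5, and that of der was 8.32 in infected replicate 3. The general stress list mean was 0.0290 in Bdellovibrio only replicate 4, near the E. coli only mean. In readings that only the value table holds, degS stood 3.02 on the log2 scale above the E. coli only median in the column numbered infected 5 and 0.42 above it in the column numbered Bdellovibrio only 3, both over the highest E. coli only value.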

How the results depend on the processing

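The settings that relabel replicate 4, keep arrays with 1 group in both sources, join all readings or weight arrays were chosen after seeing the data. Genes higher in infected than in E. coli only numbered 0 in the 3-group fit, in the value table, with replicate 4 labelled as there and with arrays of 1 group in both sources, 2 (degS and pgrR) with spots kept apart, and 0 to 1 without single replicates; the log2 change of degS stayed between 2.77 and 5.84. Lists called (4 as reported) numbered 2 with plain subtraction, median scaling, shares of summed signal, the replicate block and the value table, 3 with the dimmest 33.3% of genes left out, 0 with arrays of 1 group in both sources, and 1 to 6 without single replicates. For Bdellovibrio only against E. coli only, genes higher numbered 1 with plain subtraction, 19 in the value table, 4 with replicate 4 labelled as there, 6 with its arrays exchanged and 0 to 1 without single replicates. Genes lower numbered 0 without normalization, with the replicate block, with arrays of 1 group in both sources and with all distinct readings, 10 in the value table, 12 with replicate 4 labelled as there, 10 with its arrays exchanged and 0 to 2 without single replicates. Genes higher in infected than in Bdellovibrio only numbered 2 with replicate 4 labelled as in the value table, 5 with its arrays exchanged and 0 to 1 without single replicates. Counts outside both controls stayed at 0 in all settings run for them. Infected against E. coli only was not run without normalization. Whether the replicate numbers pair the arrays was not settled. Same-numbered residuals correlated at 0.05 to 0.33. Replicates 1, 4 and 5 correlated best with their own number (0.33, 0.10 and 0.32, against at most 0.08, 0.07 and 0.05). Replicates 2 and 3 correlated better with another number (0.34 and 0.19). With the block, 166 probes had an unadjusted limma p under 0.05 in infected against E. coli only, where 125 were reported. In Bdellovibrio only against E. coli only 629 did, where 490 were reported. The block kept 1 gene higher in infected, and with it kdpA had limma adjusted p = 0.0711 in Bdellovibrio only against E. coli only. With shares of summed signal the median of Bdellovibrio only minus E. coli only over all probes was 0.28 (0.03 as reported), and there yebV and cmoB turned to 0.21 and 0.18; yebV also turned with all distinct readings (0.0420) and ranged from -0.36 to 0.10 without single replicates. In the value table the values of hdeB, infected minus E. coli only (0.00227), amiB, infected minus E. coli only (0.0253), and yecR, Bdellovibrio only minus E. coli only (0.0326), changed sign. Apart from settings that used fewer arrays or other labels, the cause was not tested. Low signal over background limits faint genes, most on Bdellovibrio only replicate 5 (median 1.06 times background). The membrane block was not run.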

Other observations

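The tests described here were chosen after the results were seen. In Bdellovibrio only against E. coli only 3 further lists passed camera. Heat shock was lower, with 16 of 23 members lower and a median of -0.31 (adjusted p = 0.0179), as were glycolysis and gluconeogenesis, with 19 of 24 lower and a median of -0.28 (adjusted p = 0.0164), and osmotic stress, with 14 of 19 lower and a median of -0.28 (adjusted p = 0.0234). With an estimated correlation these became adjusted p = 0.193, adjusted p = 0.417 and adjusted p = 0.417. Without Bdellovibrio only replicate 5, the faintest array, the medians were -0.17 for heat shock (adjusted p = 0.0470), -0.15 for glycolysis and gluconeogenesis, which no longer passed (adjusted p = 0.124), and -0.06 for osmotic stress (adjusted p = 0.0491). Osmotic stress no longer passed without E. coli only replicate 1 (median -0.15, adjusted p = 0.0510) or 4 (median -0.27, adjusted p = 0.0566) or without Bdellovibrio only replicate 1 (median -0.20, adjusted p = 0.0828). In the value table none of these 3 passed, at adjusted p = 0.0502 for heat shock, adjusted p = 0.414 for glycolysis and adjusted p = 0.686 for osmotic stress, whose median turned to 0.04. The same held with arrays of 1 group in both sources (adjusted p = 0.107, adjusted p = 0.516 and adjusted p = 0.749, the last with a median of 0.14). Further calls were lost without normalization for heat shock and glycolysis (both adjusted p = 0.126), with array quality weights for heat shock (adjusted p = 0.0504), with shares of summed signal (adjusted p = 0.0554) or the dimmest 33.3% of genes left out (adjusted p = 0.116) for glycolysis, and with plain subtraction (adjusted p = 0.0535) or replicate 4 labelled as in the value table (adjusted p = 0.0704) for osmotic stress. The osmotic stress list holds kdpA. In infected minus Bdellovibrio only no list passed, and the smallest adjusted p was 0.106.

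With both replicate 4 arrays exchanged, 5 probes were higher in infected than in Bdellovibrio only, namely dusA, eutM, mepM, yaeQ and probe3082, which is unnamed here. With the same exchange 16 probes differed between Bdellovibrio only and E. coli only, 6 higher and 10 lower. These genes were named after their values were seen.

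Across genes the log2 changes of infected and of Bdellovibrio only against the same E. coli only arrays correlated at r = 0.590, against 0.413 in simulations of unchanged groups, and genes are not independent replicates. The covariance was 0.133 against a simulated 0.0782, a difference of 0.0551. With the E. coli only arrays split between the comparisons the median r over 20 splits was 0.211, from -0.01 to 0.346. Groups did not overlap for 20 probes (0.466%) in infected against E. coli only, for 91 (2.12%) in Bdellovibrio only against E. coli only and for 29 (0.676%) in infected against Bdellovibrio only, where chance gives 0.794%.

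Among the 312 spot pairs tied to no probe ID 0 differed between infected and E. coli only in limma, with 8 at an unadjusted p under 0.05, and 26 were above background on all 5 E. coli only arrays. The E. coli readings stored beside the infected arrays held the same density as the E. coli only files for 99.1% to 100% of spots.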
